A study of Mus musculus with 8 samples.

How the data were processed

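The count values are raw reads or fragments per Ensembl gene as deposited by the authors, 1 file per library. Per the submitters' processing notes, cutadapt, FastQC, Bowtie2 and TopHat2 were used with the mm10 build. Their versions, the program that counted reads, its annotation release and its strand setting are not given in the sources used here. Per the labels, the epidermis was separated with Dispase, and total RNA depleted of ribosomal RNA was made into directional libraries. Each file held 55487 gene rows and 5 summary rows, which were removed before any step. Genes took 35.2% to 43.3% of all rows, reads in no gene 32.9% to 42.1%, ambiguous reads 1.25% to 1.49% and reads of low alignment quality 4.44% to 5.61%. Of the gene identifiers, 55141 (99.4%) matched GENCODE M21, which is on GRCm38, the same build as mm10, and gave symbols and coordinates. The replicate libraries of a group were not identical: chi-square over degrees of freedom was 35.1, 14.7, 12.0 and 71.7 in the 4 groups.

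Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19450. Library sizes were scaled by TMM, with factors from 0.911 to 1.05. All 8 libraries were fitted in a single model with a mean per group, and each comparison was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. The biological coefficient of variation was 0.165, the residual degrees of freedom 4 and the prior degrees of freedom 4.23. A gene was called at Benjamini-Hochberg adjusted p under 0.05. The difference of responses is the DMBA/TPA log2 fold change minus the DMBA log2 fold change, each against its own acetone group. SE is the absolute log2 fold change over the square root of F. CPM values use TMM-scaled library sizes, and ± after a CPM mean is the SD of 2 libraries.

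Lists of genes were written before the data were examined: 39 lists, of which 38 had at least 5 measured members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The neutrophil list had 3 measured members and was not tested. Of 613 named entries, 568 were measured. Camera was repeated with the correlation estimated from the residuals, and fry was run as another test. Counts adjusted over the list alone use Benjamini-Hochberg over the list members only.

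Named genes were taken by a rule fixed in advance: among called genes with a mean of at least 5 CPM over the libraries compared, both treated libraries on the same side of both acetone libraries (not asked of the difference) and a symbol that is no predicted gene, pseudogene, small RNA or receptor segment, up to 12 per direction with the largest change in the DMBA and DMBA/TPA comparisons and 5 per direction in the others. Up to 4 members per list with the smallest adjusted p and a fixed set of 12 genes were added. Some genes that this rule takes are not reported here. Eligible were 26 higher and 9 lower genes for DMBA, 2887 and 2258 for DMBA/TPA, 1006 and 528 for the difference and 293 and 440 between the acetone groups. Genes named for the overlap were chosen after their values were seen. For genes with 0 counts in a group, the fold is at least the ratio over a floor of 3 counts for that group. For 1 to 3 counts, it is the ratio with its exact 95% counting interval. Floors and intervals cover counting error only, and fitted fold changes of such genes are no bounds. Calls of genes that overlap others on the same or the opposite strand, or that have near-identical copies, are uncertain because the strand setting is not known.

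The pipeline was tested on simulated data, drawn from the genes' means, trended dispersions and library sizes with changes put in. Each gene was drawn independently, with the same dispersion in all groups and no scatter of genes around the trend. For DMBA, 48 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were recovered, with 10 of 19229 unchanged genes called. For DMBA/TPA it was 52, 76 and 6, and for the difference of responses 28, 56 and 1. A shifted list was recovered each time, and 1, 0 and 0 unshifted lists were called. Since the simulated genes were not correlated, these list counts do not cover false list calls where members move together. Nor do the gene counts cover groups that differ in spread, or genes whose spread departs from the trend.

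Alternatives tried were RLE size factors, total counts, no low-count filter, the DESeq2 1.42.0 Wald test, limma voom, a 2-fold minimum, the sample number as a replicate block, a fit of the compared groups only, all 4 acetone libraries as a single control group, and leaving out each library. The other acetone group as control was added after seeing the data. Gene span is the distance from the start to the end of a gene in the annotation.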

Results

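RNA from mouse dorsal skin epidermis was sequenced in 8 libraries, 2 in each of 4 groups. DMBA is a polycyclic aromatic hydrocarbon whose metabolites form DNA adducts and which initiates skin tumours in mice. TPA is a phorbol ester that activates protein kinase C and acts as a tumour promoter. The FVB mice were 7 to 8 weeks old. The DMBA group received a single application of 100 µl at 1 mg/ml and was harvested on day 10. In the DMBA/TPA group, DMBA was followed by TPA at 0.1 mg/ml 2 times per week, with harvest on day 52. Each regimen has its own acetone-treated group, named here Control DMBA and Control DMBA TPA after the sample titles. The labels do not give the harvest day of the acetone groups, and nothing in them says that the 2 libraries of a group come from separate animals. All p-values therefore measure only the spread between these libraries, which may be technical.

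Counts assigned to genes came to 32610374 and 34842013 in Control DMBA, 30463506 and 36002886 in DMBA, 28592432 and 35266002 in Control DMBA TPA, and 26300400 and 28042551 in DMBA/TPA. Of 55487 genes in the files, 19450 had enough counts to be tested. The principal component that held 55.8% of the variance placed DMBA/TPA 1 and 2 at 81.5 and 108.9 and Control DMBA TPA 1 and 2 at -90.1 and -84.1. The 4 libraries of the DMBA set lay between -13.6 and 8.84 on it.

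**Figure D1:**
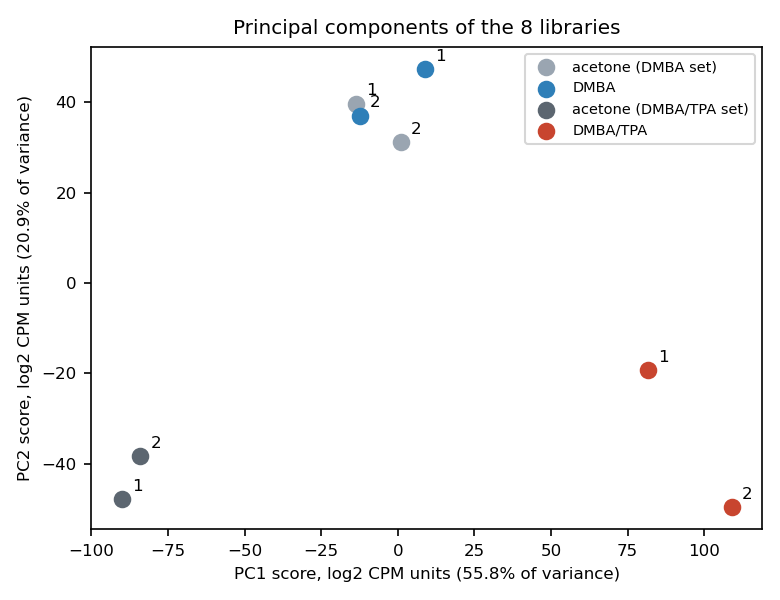
Scores of the 8 libraries on the leading principal components of log2 CPM, with the replicate number beside each point. DMBA/TPA (81.5 and 108.9) and Control DMBA TPA (-90.1 and -84.1) lie at opposite ends of the horizontal axis, and DMBA lies near Control DMBA.

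The DMBA comparison asks what a single carcinogen application left in the epidermis at day 10. Interferon response genes were higher: Oasl2, an oligoadenylate synthetase-like antiviral protein (ENSMUSG00000029561, mm10 chromosome 5, 114896936 to 114912234), went from 2.22 ± 0.979 CPM (SD, n = 2) in Control DMBA to 21.8 ± 0.53 CPM (n = 2) in DMBA. Egln3, a prolyl hydroxylase that acts on the hypoxia-inducible factors (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), went from 84.2 ± 0.252 to 266 ± 42.5 CPM. The collagen genes Col3a1 and Col1a2 were lower: Col3a1, a fibrillar collagen of connective tissue (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), went from 249 ± 150 to 3.60 ± 0.627 CPM. Keratin genes tied to thickened epidermis did not pass the test, with Krt16 at 0.72 ± 0.46 on the log2 scale (SE, adjusted p = 0.763).

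By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 52 genes were called in the DMBA comparison, 37 higher and 15 lower. Among the genes taken by the naming rule, the largest increases, as log2 fold change ± SE, were those of Pyy, a gut peptide hormone (4.75 ± 0.40, adjusted p = 0.00914), the immunity-related GTPase Iigp1 (4.52 ± 0.49, adjusted p = 0.0187) and the adhesion molecule Igsf9b (3.37 ± 0.26, adjusted p = 0.008). Oasl2 followed with 3.30 ± 0.31 (adjusted p = 0.0165) and Igfl3, an insulin-like growth factor family member, with 2.70 ± 0.18 (adjusted p = 0.00527). Gbp2 and Gbp7, guanylate-binding proteins of cell-autonomous immunity, rose by 2.61 ± 0.33 and 1.61 ± 0.22, and the antiviral helicase Ddx60 by 2.12 ± 0.22. Igtp and Irgm2, immunity-related GTPases whose genes overlap each other so that their reads are hard to assign, had 2.09 ± 0.22 and 1.79 ± 0.23. Egln3 had 1.66 ± 0.14 (adjusted p = 0.00914) and Ube2l6, the conjugating enzyme for Isg15, 1.63 ± 0.24 (adjusted p = 0.0467). Large decreases were in Col3a1 (-6.12 ± 0.62, adjusted p = 0.0168), Col1a2 (-4.13 ± 0.58, adjusted p = 0.0402) and Carns1, carnosine synthase (-3.28 ± 0.48, adjusted p = 0.0467). The cytochrome P450 gene Cyp2g1 (-3.20 ± 0.37), the carboxylesterase gene Ces1d (-2.96 ± 0.31) and Fam57b (-2.56 ± 0.31) were also lower. Paqr7, a membrane progestin receptor, had -2.11 ± 0.23, the vasopressin receptor gene Avpr1a -1.74 ± 0.21, and Fam213a -0.92 ± 0.12. In all 52 called genes, both DMBA libraries lay beyond both Control DMBA libraries. With 2 libraries per group the call itself largely requires this, so it is no separate support. All groups share the estimate of spread and the low-count filter, so libraries outside this comparison also affect its calls. The count rests on single libraries: it was 26 and 24 without Control DMBA 1 and 2, 4 and 6 without DMBA 1 and 2, 28 and 25 without Control DMBA TPA 1 and 2, and 176 and 168 without DMBA/TPA 1 and 2. The share of higher genes, 71.2%, was 50% and 45.8% without Control DMBA 1 and 2, 52.1% by DESeq2 and 47.8% without the low-count filter. Without DMBA 1 the adjusted p was 0.0988 for Oasl2, 0.145 for Col3a1, 0.0539 for Egln3 and 0.0603 for Pyy, and without DMBA 2 it was 0.108 for Oasl2 and 0.184 for Col3a1. For Col1a2 it was 0.42 and 0.292 without DMBA 1 and 2, 0.0732 without Control DMBA 1, and 0.0724 and 0.0717 without Control DMBA TPA 1 and 2. Without DMBA 1, 2 of the 24 named genes called here kept their call, and without DMBA 2, 5 did. Without Control DMBA 1 and 2, 13 and 8 kept it, and without Control DMBA TPA 1 and 2, 17 and 16.

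Of 20 measured interferon response genes, 8 rose, none fell and 12 were not called over all genes tested, with 17 higher when adjusted over the list alone. The list was called higher by camera (median log2 fold change 2.25, adjusted p = 6.47e-60; adjusted p = 0.0427 with an estimated correlation), and it kept its call without each of the 8 libraries. Besides Oasl2, Cxcl9, a chemokine induced by interferon gamma, rose by 2.63 on the log2 scale (adjusted p = 0.0187) and Isg15, a ubiquitin-like modifier, by 2.47 ± 0.29 (adjusted p = 0.0205). Over the 12 alternatives run per gene, the adjusted p of Oasl2 ranged from 1.87e-22 to 0.108, that of Cxcl9 from 1.86e-06 to 0.184 and that of Isg15 from 7.65e-09 to 0.184. Without DMBA 1 all 3 calls were lost (adjusted p = 0.0988, 0.129 and 0.145), as they were without DMBA 2 (0.108, 0.184 and 0.184). Without Control DMBA 1 and 2, Cxcl9 had 0.0537 and 0.0702, and Isg15 0.0765 and 0.0702. Against the other acetone set, a comparison chosen after seeing the data, the list median was 2.29.

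**Figure D2:**
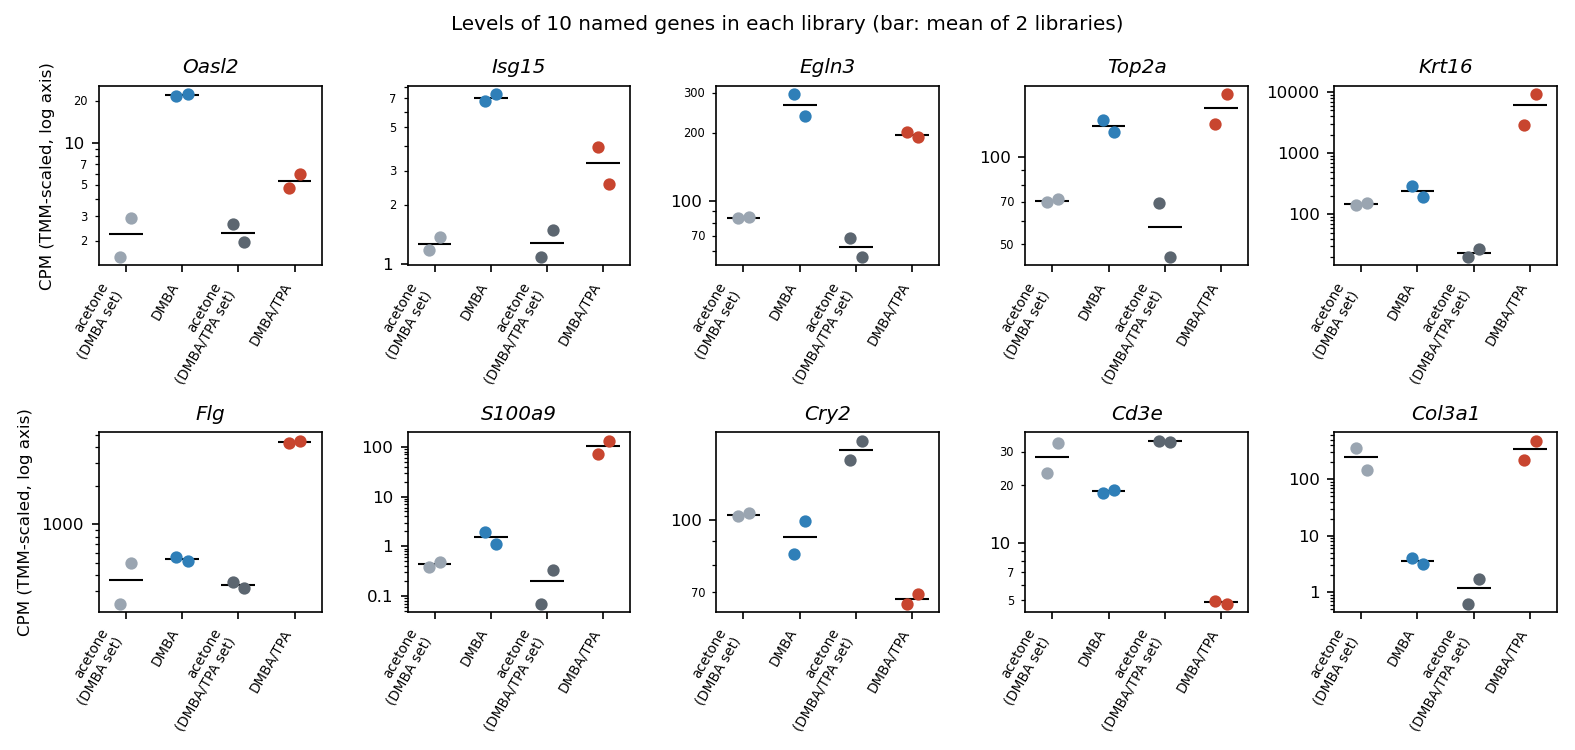
CPM of 10 named genes in each library on log axes, with points for libraries and a bar for the mean of 2. Oasl2 is highest in DMBA (21.8 CPM), Krt16 in DMBA/TPA (6058 CPM), and Col3a1 is near 1 CPM in Control DMBA TPA (1.18 CPM) and near 3.6 CPM in DMBA.

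The list of G2/M and mitosis genes was called higher after DMBA (median 0.85, adjusted p = 3.38e-22; adjusted p = 0.233 with an estimated correlation). By edgeR none of its 20 measured members was called over all genes, and 19 were higher when adjusted over the list alone. Cdk1, the mitotic kinase, had 0.80 (adjusted p = 0.134), Top2a, a DNA topoisomerase of dividing cells, 0.85 (adjusted p = 0.155), and Bub1, a spindle checkpoint kinase, 0.98 (adjusted p = 0.164). Mki67, a marker of cycling cells, had 0.76 (adjusted p = 0.239). DESeq2 called each of these 4 (adjusted p = 0.00918, 0.00358, 0.02 and 0.0236), and over 12 alternatives the highest values were 0.775, 0.782, 0.89 and 1. Of 16 glycolysis and hypoxia genes, Egln3 alone was called over all genes by edgeR and 3 were higher when adjusted over the list alone. That list had a median of 0.37 (adjusted p = 1.86e-13; adjusted p = 0.232 with an estimated correlation), and Vegfa, the angiogenic growth factor, had 1.06 (adjusted p = 0.0929). Vegfa was called without DMBA/TPA 1 (0.0325) and 2 (0.0336) and by DESeq2 (7.71e-05), and its highest value over 12 alternatives was 0.576. Lists of DNA replication genes (median 0.18, adjusted p = 0.00045) and p53 targets (median 0.28, adjusted p = 0.000802) were called higher with no member called over all genes or over the list alone. With an estimated correlation their adjusted p = 0.696 and 0.233. Against the other acetone set neither list was called, with adjusted p = 0.221 and 0.363. The p53 target Pmaip1, a pro-apoptotic protein, had 0.69 (adjusted p = 0.251), and Cdkn1a, the p21 cell cycle inhibitor, had 0.17 (adjusted p = 0.794). The alarmin and antimicrobial list was called higher (median 0.67, adjusted p = 0.00119; adjusted p = 0.504 with an estimated correlation), with 1 of 12 members higher over the list alone. That call was lost without Control DMBA 1 (adjusted p = 0.368) and without DMBA 1 (adjusted p = 0.0504). The ribosomal protein list was at the threshold (median 0.08, adjusted p = 0.0495; adjusted p = 0.788 with an estimated correlation). It was lost without Control DMBA 1 (0.879), DMBA 2 (0.161), Control DMBA TPA 1 (0.0538) and Control DMBA TPA 2 (0.0583).

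Sebaceous gland genes were lower after DMBA (median -1.45, adjusted p = 9.48e-21; adjusted p = 0.232 with an estimated correlation), with 1 of 14 members called and 11 lower when adjusted over the list alone. Scd3, a stearoyl-CoA desaturase of sebocytes, fell by 3.57 ± 0.44 on the log2 scale (adjusted p = 0.0227), and the melanocortin receptor gene Mc5r had -2.16 (adjusted p = 0.0929). Mc5r was called without DMBA/TPA 1 (0.00557) and 2 (0.00528) and by DESeq2 (7.95e-07), and its highest value over 12 alternatives was 0.513. The Scd3 call was lost without DMBA 1 (adjusted p = 0.0999), Control DMBA 1 (0.0636) and 2 (0.0605) and Control DMBA TPA 1 (0.0724) and 2 (0.0716), and over 12 alternatives its adjusted p ranged from 1.53e-11 to 0.0999. Markers of cells from outside the epidermis moved in the same comparison. Of 13 fibroblast genes, 2 fell (Col3a1 and Col1a2), and 8 were lower and 1 higher when adjusted over the list alone. The fibroblast list had a median of -2.60 (adjusted p = 1.26e-14; adjusted p = 0.232 with an estimated correlation). The endothelial list (median -1.76, or -1.75 with members at 0 counts set at their bound) and the mast cell list (median -7.79, or -4.40 at the bound) were also called lower, with adjusted p = 8.33e-13 and 8.59e-09. With an estimated correlation, adjusted p = 0.233 and 0.232. No member of either was called over all genes, and 11 of 12 and 5 of 6 were lower when adjusted over the list alone. Control DMBA 1 stood above Control DMBA 2 in summed CPM of fibroblast (1965 against 954.5), endothelial (22.1 against 11.75) and mast cell genes (9.498 against 1.226). The adipocyte list (median -2.18, adjusted p = 1.02e-07) and the erythroid list (median -0.96, adjusted p = 0.000954) were called lower too, with 3 of 6 members of each lower over the list alone. With an estimated correlation, adjusted p = 0.0867 and 0.232. These calls did not hold against the other acetone set, where adjusted p was 0.117 for fibroblast genes (median 0.68), 0.37 for endothelial, 0.629 for mast cell, 0.943 for adipocyte and 0.942 for erythroid genes.

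Genes of the hair shaft and inner root sheath were called lower after DMBA as a list (median -1.41, adjusted p = 0.000434; adjusted p = 0.736 with an estimated correlation), with none of its 23 members called over all genes. The call was lost without Control DMBA 2 (adjusted p = 0.475) and without DMBA 2 (adjusted p = 0.114), and against the other acetone set the list was called in the other direction (median 4.03, adjusted p = 5.48e-08). Targets of the aryl hydrocarbon receptor, the sensor of compounds such as DMBA, were not called (median -0.27, adjusted p = 0.191), with 1 of 9 lower when adjusted over the list alone. Cyp1a1, the best known of these targets, had -1.67 ± 0.40 (adjusted p = 0.171), and was called without DMBA/TPA 1 (0.0355) and DMBA/TPA 2 (0.0356) and by DESeq2 (0.000854). Lists of basal (adjusted p = 0.191), suprabasal (0.375) and granular or cornified envelope (0.218) keratinocyte genes were not called, nor were barrier lipid (0.296), hyperplasia keratinocyte (0.191) or circadian clock genes (0.183). T cell genes were not called (median -0.43, adjusted p = 0.101), with 2 higher and 4 lower of 20 when adjusted over the list alone. The T cell list was called lower without Control DMBA 1 (adjusted p = 0.000309) and without DMBA 1 (0.0148). Also not called were lists of NRF2 targets (0.154), ERK and AP-1 response (0.559), EGF receptor ligands (0.146), cytokines (0.0622), prostanoid and polyamine enzymes (0.533), proteases (0.533), papilloma progression (0.533), glucocorticoid response (0.538), chromatin regulators (0.482) and mitochondrially encoded genes (0.558). The same held for MHC class II (0.181), Langerhans cell (0.181), macrophage (0.533), melanocyte (0.0695), skeletal muscle (0.951) and follicle stem cell or outer sheath genes (0.558). In the prostanoid, macrophage and outer sheath lists the median had the other sign than the test. Of the 24 lists not called, 14 were called on leaving out at least 1 library. Among genes fixed for reporting, Hras, the proto-oncogene often mutated by DMBA, had 0.05 (adjusted p = 0.984), Krt6a 0.26 (0.98), Krt10 -0.17 (0.958), Krt14 0.23 (0.958), Odc1 0.19 (0.986), Ptgs2 -0.62 (0.792), S100a8 -0.04 (1) and S100a9 1.78 (0.301).

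The DMBA/TPA comparison asks what DMBA followed by repeated TPA left in the epidermis at day 52. Keratins of thickened and wounded epidermis rose steeply: Krt16 (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902) went from 23.5 ± 5.0 CPM (SD, n = 2) to 6058 ± 4491 CPM (n = 2), and Krt6a from 166 ± 94.7 to 6150 ± 4315 CPM. Flg, the filaggrin precursor of the granular layer (ENSMUSG00000102439, chromosome 3, 93273523 to 93293686), went from 337 ± 24.2 to 4421 ± 113 CPM. Cd3e, a T cell receptor subunit (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627), went from 34.1 ± 0.27 to 4.87 ± 0.126 CPM. The clock gene Cry2 went from 141 ± 9.27 to 67.7 ± 2.24 CPM.

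The same test called 7917 genes, 4356 higher and 3561 lower, and 3860 at 2-fold or more. Total counts in place of TMM scaling turned the balance to 3675 higher and 4489 lower of 8164, that is 45.0% higher in place of 55%, and moved the median of all genes from -0.003 to -0.12. Without Control DMBA TPA 1 and 2 the count was 3704 and 4369, and without DMBA/TPA 2 it was 4829. With the 4 acetone libraries as a single control group it was 4632. Against the other acetone set, an alternative chosen after seeing the data, it was 3766, of which 3040 were called in the same direction as in the main comparison (1879 higher, 1161 lower) and 28 in the opposite direction. In all 7917 called genes, both DMBA/TPA libraries lay beyond both Control DMBA TPA libraries, which the call itself largely requires and which is no separate support.

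The largest increases under the naming rule were in genes at or near 0 counts in Control DMBA TPA, so they are given as bounds over a floor of 3 counts for the group, or as ratios with 95% counting intervals, which cover counting error only. Chil4, a chitinase-like secreted protein, had 16673 counts against 2, a ratio of 10650 [2947, 87910]. Fabp4, a fatty acid-binding protein of adipocytes and endothelium, had 7071 against 2, a ratio of 4515 [1249, 37290]. Cornified envelope genes with 0 counts in Control DMBA TPA were at least 701-fold (Sprr2i), 421.8-fold (Sprr2b), 342-fold (Sprr2f), 474-fold (Lce3d) and 335-fold (Lce3b) higher. The Sprr2 and Lce families hold near-identical copies, so the split between their members is uncertain. Il19, a cytokine of the interleukin-10 family, was at least 298-fold higher (adjusted p = 0.00123; 0.0538 by DESeq2, the highest of its 12 alternatives, from 0.000499). Hair follicle keratin genes Krt72 and Krt26 were at least 605-fold and 540-fold higher, and the hair keratin-associated gene Krtap11-1 at least 358-fold. In Control DMBA these genes were not near 0: Krt72 had 1951 counts there against 1422 in DMBA/TPA, Krt26 826 against 1268 and Krtap11-1 254 against 842. Krtap7-1, of the same family, had 982 counts in DMBA/TPA against 0 in Control DMBA TPA, and 1146 in Control DMBA. The Krtap11-1 call was lost without Control DMBA TPA 1 (adjusted p = 0.0581) and 2 (adjusted p = 0.057). The largest decreases under the naming rule, which leaves out receptor segments, were in Ifitm6 (-6.72 ± 0.44, adjusted p = 0.000213) and the kainate receptor gene Grik1 (-6.21 ± 1.15, adjusted p = 0.00477). The laminin gene Lama1 (-5.27 ± 0.22, adjusted p = 5.45e-05) and the sodium channel gene Scn3a (-5.22 ± 0.49, adjusted p = 0.000466) followed. Prf1, the pore-forming protein of cytotoxic cells, had -4.97 ± 0.23 (adjusted p = 7.53e-05) and Trat1, a T cell receptor adaptor, -4.49 ± 0.30 (adjusted p = 0.000213). Tgm7, a transglutaminase, had -4.86 ± 0.38, Dab1, an adaptor of reelin signalling, -4.80 ± 0.42, and Hamp2, a hepcidin, -4.37 ± 0.39. The potassium channel gene Kcnma1 (-4.36 ± 0.37), the cation channel gene Trpm3 (-4.27 ± 0.44) and the tropomodulin gene Tmod2 (-4.02 ± 0.93) completed the set. The Tmod2 call was lost without DMBA/TPA 2 (adjusted p = 0.0561) and Control DMBA TPA 2 (adjusted p = 0.0534).

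All 19 measured genes of the hyperplasia and stress keratinocyte list rose (median 8.58, or 8.01 at the bound; adjusted p = 3.43e-22; adjusted p = 0.25 with an estimated correlation). Krt16 had 8.01 ± 0.62 (adjusted p = 0.000322), Krt6b 10.44 ± 0.93 (adjusted p = 0.000429), Sprr2d 8.16 ± 0.61 (adjusted p = 0.000316), Serpinb3a, a serine protease inhibitor, 6.64 ± 0.62 (adjusted p = 0.000466) and Krt6a 5.21 ± 0.62 (adjusted p = 0.000969). The Krt6 genes are near-identical copies, so their split is uncertain. Of 12 alarmin and antimicrobial genes, 11 rose (median 7.28, or 6.66 at the bound; adjusted p = 2.39e-14; adjusted p = 0.25 with an estimated correlation). They included S100a9 (8.88 ± 0.53) and S100a8 (5.45 ± 0.53), which form calprotectin, Slpi, a secreted protease inhibitor (9.48 ± 0.73), and Chil1 (6.75 ± 0.47). Stfa2, a stefin, had a ratio of 2574 [712.1, 21260] and belongs to a family of near-identical copies. Granular and cornified envelope genes rose in 15 of 21 cases, with 17 higher when adjusted over the list alone (median 1.73, adjusted p = 2.65e-15; adjusted p = 0.122 with an estimated correlation). Flg had 3.71 ± 0.31, Casp14, a caspase of cornification, 3.33 ± 0.23, Lce1d 2.90 ± 0.19 and Asprv1, a protease that processes filaggrin, 2.38 ± 0.14. Barrier lipid genes rose in 11 of 14 cases (median 0.90, adjusted p = 1.28e-05; adjusted p = 0.31 with an estimated correlation), among them the sphingomyelinase gene Smpd1 (1.36), the ceramide synthase gene Cers3 (1.36) and Ugcg (1.08). Basal and suprabasal keratinocyte lists were not called (adjusted p = 0.763 and 0.411). Within them Krt14 rose by 2.27 ± 0.33 (adjusted p = 0.00205), while Krt15, a keratin of quiescent basal cells, fell by 1.73 and Dst, a hemidesmosome linker, by 1.09 on the log2 scale. Krt10, the main keratin of the spinous layer, had -0.16 ± 0.24 (adjusted p = 0.605). The basal list was called higher without DMBA/TPA 1 (adjusted p = 0.0193).

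All 20 measured G2/M and mitosis genes rose after DMBA/TPA (median 1.85, adjusted p = 3.21e-14; adjusted p = 0.296 with an estimated correlation), including Aurka, a mitotic kinase (2.42), Ccnb1, the mitotic cyclin (2.00), the spindle motor gene Kif11 (1.92) and Cdk1 (1.59 ± 0.17). Mki67 rose by 1.22 ± 0.22 (adjusted p = 0.00406). Between the acetone sets the mitosis list was lower in Control DMBA TPA (median -0.50, camera adjusted p = 0.000307), with a median of -0.22 without Control DMBA TPA 2. In DMBA/TPA against DMBA directly its median was 0.38. The DNA replication list was not called (adjusted p = 0.433), with 7 of 21 members higher and 2 lower. Ccne1, the cyclin of S phase entry, had 2.17 and Rrm2, a ribonucleotide reductase subunit, 1.41. Of 16 prostanoid and polyamine genes, 8 rose and 2 fell, and the list was not called (adjusted p = 0.0614). Odc1, the rate-limiting enzyme of polyamine synthesis, rose by 2.38 ± 0.53 (adjusted p = 0.00934), a call lost without Control DMBA TPA 1 (adjusted p = 0.0738). Alox8, an arachidonate lipoxygenase, rose by 3.90, Smox, spermine oxidase, by 2.98 and Ptges, a prostaglandin E synthase, by 2.06. Ptgs2, the inducible cyclooxygenase, had 0.93 ± 0.40 (adjusted p = 0.0924) and was called without DMBA/TPA 1 (adjusted p = 0.00243). The prostanoid list was called without Control DMBA 1 and 2, DMBA 1 and 2, and DMBA/TPA 1 (adjusted p = 0.0269, 0.0262, 0.0434, 0.0459 and 0.00382). Hras had 0.32 ± 0.13 (adjusted p = 0.0874) and was called without DMBA/TPA 1 (adjusted p = 0.00577). Of 14 papilloma progression genes, 6 rose and 1 fell (adjusted p = 0.0767). That list was called without DMBA 1 and 2 and without DMBA/TPA 1 and 2 (adjusted p = 0.0454, 0.0473, 0.00144 and 0.0157). Pitx1, a transcription factor, had a ratio of 1622 [448.7, 13400], the keratin gene Krt18 rose by 2.88 and the integrin gene Itgb6 by 1.33.

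Protease and matrix remodelling genes rose in 16 of 18 cases and fell in 1 (17 and 1 over the list alone; median 3.23, adjusted p = 1.3e-12; adjusted p = 0.296 with an estimated correlation). The kallikrein protease genes Klk13, Klk6 and Klk9 had 8.03, 6.79 and 3.99, and Tnc, an extracellular matrix glycoprotein of wounds, 2.32 ± 0.15. Epidermal cytokine genes rose in 13 of 16 cases, 14 when adjusted over the list alone (median 2.19, adjusted p = 4.1e-08; adjusted p = 0.25 with an estimated correlation). The interleukin-36 family genes Il1f6, Il1f9 and Il1f8 had 6.38, 2.44 and 2.21, and Il24 had a ratio of 896.5 [160.4, 35460]. Among 11 ligands and receptors of the EGF receptor family, 6 rose and 2 fell (median 1.20, adjusted p = 0.0184; adjusted p = 0.31 with an estimated correlation). Hbegf rose by 3.94, Nrg1 by 2.47 and Tgfa by 1.61, while Btc fell by 2.10. Of 23 ERK and AP-1 response genes, 12 rose and 1 fell (median 0.56, adjusted p = 0.00951; adjusted p = 0.529 with an estimated correlation), with Phlda1 at 2.80 and Junb at 1.59. NRF2 targets of the oxidative stress response rose in 10 of 17 cases and fell in 2, or 11 and 3 over the list alone (median 1.13, adjusted p = 0.000413; adjusted p = 0.296 with an estimated correlation). They included Gsta4 (5.23), the cystine transporter gene Slc7a11 (4.70), Akr1b8 (3.36) and the haem oxygenase gene Hmox1 (1.43). Glycolysis and hypoxia genes rose in 12 of 16 cases, 13 over the list alone (median 1.49, adjusted p = 6.31e-10; adjusted p = 0.25 with an estimated correlation), with Hk2 at 2.87, Vegfa at 2.32 and Egln3 at 1.65. Interferon response genes rose in 13 of 20 cases and fell in 1, or 14 and 1 over the list alone (median 1.40, adjusted p = 0.000403; adjusted p = 0.306 with an estimated correlation). Oasl1 had a ratio of 307.8 [54.72, 12210], Gbp3 3.00 and Cxcl9 1.92, while Usp18, a protease that removes Isg15, fell by 1.61. Lists of aryl hydrocarbon receptor and p53 targets were not called (adjusted p = 0.909 and 0.668), with 3 of 9 higher and 2 lower, and 7 of 21 higher and 4 lower. Cyp1a1 had -0.68 (adjusted p = 0.194), and was called without DMBA/TPA 1 (0.0104), while Btg2 rose by 0.74 and Fas fell by 1.84. Cdkn1a rose by 0.43 ± 0.12 (adjusted p = 0.0198), a call lost without DMBA/TPA 2 (adjusted p = 0.0845), Control DMBA TPA 1 (0.0958) and Control DMBA TPA 2 (0.111).

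Circadian clock genes fell in 12 of 15 cases after DMBA/TPA, with none higher (median -1.06, adjusted p = 3.8e-07; adjusted p = 0.25 with an estimated correlation). The clock repressor genes Cry2, Per2 and Per3 had -1.06 ± 0.11, -1.10 and -1.06, and Tef, an output transcription factor, -1.10. Against the other acetone set the median was -0.60 (adjusted p = 0.000626), and between the acetone sets clock genes were higher in Control DMBA TPA (median 0.46, adjusted p = 0.000225; adjusted p = 0.408 with an estimated correlation). The labels give no time of day. Glucocorticoid response genes fell in 6 of 12 cases (median -0.44, adjusted p = 0.0121; adjusted p = 0.25 with an estimated correlation), and the list was not called against the other acetone set (adjusted p = 0.138). The mineralocorticoid and glucocorticoid receptor genes Nr3c2 and Nr3c1 fell by 3.27 and 1.31 on the log2 scale. Of 16 chromatin regulators of the epidermis, 4 fell and 1 rose, and the list was not called (adjusted p = 0.113). The genome organiser gene Satb1 had -2.08 and the Polycomb gene Bmi1 -1.08. Mitochondrially encoded genes fell in 3 of 12 cases (median -0.65, adjusted p = 0.0278; adjusted p = 0.642 with an estimated correlation). That call was lost without DMBA/TPA 2 (adjusted p = 0.136), in which mitochondrial genes took 0.742% of gene counts, against 1.70% to 2.24% in the other 7 libraries. Ribosomal protein genes rose in 17 of 28 cases, 20 over the list alone (median 0.47, adjusted p = 3.7e-05; adjusted p = 0.505 with an estimated correlation), with Rps2 at 1.23. The members of this list have a median span of 4.24 kb, and protein-coding genes of up to 4.184 kb and of 4.184 to 7.758 kb had medians of 0.50 and 0.31. Other lists called higher also had short median spans: hyperplasia (1.94 kb), mast cell (3.01), alarmin (4.56) and granular genes (5.07). So did cytokine (6.52), ERK and AP-1 (6.71) and hair shaft genes (7.38). The T cell (5.88 kb) and mitochondrially encoded lists (0.871 kb) were short too and were called lower.

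T cell genes, including those of dendritic epidermal T cells, fell in 12 of 20 cases and rose in 5, or 13 and 5 over the list alone (median -1.57, adjusted p = 9.98e-08; adjusted p = 0.296 with an estimated correlation). The gamma delta receptor segment Trdv4 had -5.31, and the receptor subunit genes Cd247, Cd3g and Cd3e had -3.32, -2.86 and -2.81 ± 0.18. Macrophage and monocyte genes rose in 11 of 15 cases and fell in 1 (median 3.78, adjusted p = 1.28e-05; adjusted p = 0.296 with an estimated correlation). Between the acetone sets that list was lower in Control DMBA TPA (median -1.71, camera adjusted p = 0.0173), with a median of -0.778 without Control DMBA 2. Its summed CPM was 103.8 and 74.09 in Control DMBA TPA 1 and 2 and 102.6 and 146.7 in DMBA/TPA 1 and 2. The complement gene C1qb had a ratio of 212 [37.53, 8423] and the lipopolysaccharide co-receptor gene Cd14 rose by 3.36, while Adgre1, the F4/80 antigen, fell by 2.86. The Langerhans cell list was not called (adjusted p = 0.86): H2-M2 fell by 1.77 and Itgax rose by 1.61. The MHC class II list was not called (0 higher and 3 lower of 9, adjusted p = 0.153), and was called lower without Control DMBA TPA 2 (adjusted p = 0.0435) and DMBA/TPA 2 (0.026).

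Markers of dermal cells rose in the same comparison. Fibroblast genes rose in 10 of 13 cases, 11 over the list alone (median 4.76, adjusted p = 1.46e-07; adjusted p = 0.296 with an estimated correlation). Col3a1 went from 1.18 CPM in Control DMBA TPA to 347 ± 187 CPM (8.15 ± 0.71, adjusted p = 0.000407), against 249 ± 150 CPM in Control DMBA, and Col1a1 and Col5a1 rose by 6.55 and 4.76. Endothelial genes rose in 10 of 12 cases (median 5.25, or 5.03 at the bound; adjusted p = 3.3e-07; adjusted p = 0.31 with an estimated correlation), with Pecam1 at 5.34 and Plvap at 5.15. Of 6 mast cell genes, 4 rose, 5 over the list alone (median 7.05, or 3.89 at the bound; adjusted p = 0.00543; adjusted p = 0.352 with an estimated correlation), and the tryptase gene Tpsab1 was at least 20.9-fold higher. Erythroid (adjusted p = 0.141) and skeletal muscle (0.894) lists were not called. The erythroid list was called without DMBA/TPA 1 (0.0493). The adipocyte list was not called (adjusted p = 0.763), and its median of -0.15 had the other sign than its test, as had that of the outer sheath list (-0.13). Against the other acetone set the fibroblast and endothelial lists kept their calls (medians 0.87 and 2.23, adjusted p = 0.0447 and 0.00283) and the mast cell list did not (adjusted p = 0.359).

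Hair shaft and inner root sheath genes rose in 20 of 23 cases after DMBA/TPA (median 7.92, or 7.67 at the bound; adjusted p = 9.98e-08; adjusted p = 0.417 with an estimated correlation). The hair keratin genes Krt81 and Krt34 had ratios of 2411 [432.2, 95280] and 1905 [341.4, 75310], Krt86 rose by 9.04 (7.00 to 13.35 over 12 alternatives), and Padi3, a deiminase of the hair shaft, by 9.64 (8.82 to 13.95). Summed CPM of the list was 3489 in DMBA/TPA 1 and 521.6 in DMBA/TPA 2. Melanocyte genes rose in 7 of 11 cases, 8 over the list alone (median 2.62, adjusted p = 0.000413; adjusted p = 0.359 with an estimated correlation), with the melanosome genes Pmel at 3.14 and Dct at 1.77. Neither list was called against the other acetone set (adjusted p = 0.148 for hair shaft, 0.372 for melanocyte genes). The list of hair follicle stem cell and outer root sheath genes was not called (4 higher and 4 lower of 15, adjusted p = 0.801). Among sebaceous gland genes, Scd3 had -4.02. It was also higher in Control DMBA TPA than in Control DMBA, by 3.64 to 3.88 over 12 alternatives. As a list, sebaceous gland genes were called lower by camera (2 of 14 lower, median -0.42, adjusted p = 0.044; adjusted p = 0.642 with an estimated correlation). That call was lost without Control DMBA TPA 2 (0.15) and DMBA/TPA 2 (0.151).

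**Figure D3:**
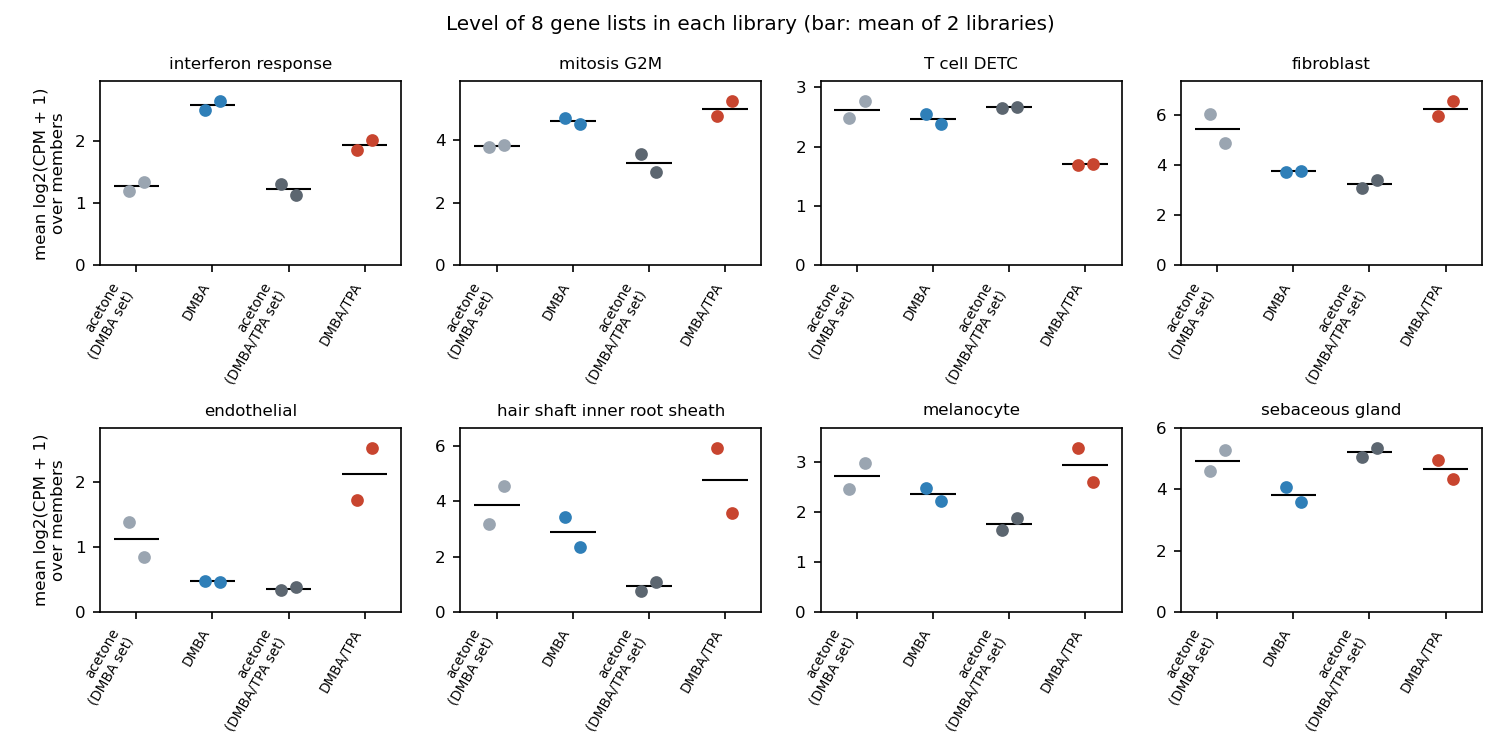
Mean log2(CPM + 1) over the members of 8 gene lists in each library, with points for libraries and a bar for the mean of 2. The fibroblast list stands at 6.02 and 4.85 in Control DMBA, 3.72 and 3.76 in DMBA, 3.08 and 3.41 in Control DMBA TPA, and 5.93 and 6.53 in DMBA/TPA.

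Between DMBA and DMBA/TPA, each against its own acetone group, 17 genes were higher in both, where 8.29 would be called higher in both by chance (Fisher's exact test, p = 0.00136), and 9 were lower in both, where chance gives 2.75 (p = 0.000393). No gene was higher after DMBA and lower after DMBA/TPA, where chance gives 6.77. The 17 included Oasl2, Isg15, Cxcl9, Egln3 and Igsf9b, and the 9 included Scd3, Hamp2, Cyp2g1 and Ces1d. Scd3 and Hamp2 were themselves higher in Control DMBA TPA than in Control DMBA. Over 12 alternatives that gap was 3.64 to 3.88 and 2.28 to 3.09 on the log2 scale. Their falls in DMBA/TPA therefore depend largely on the acetone group used. Genes are not independent replicates, so these p-values are too small where genes move together. Both comparisons also use the same estimate of spread for each gene, which can make joint calls likelier than the chance counts assume. Lower after DMBA and higher after DMBA/TPA were 4 genes, Col3a1, Col1a2, Ccdc80 and Mfap4, where chance gives 3.36.

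The difference of the responses asks whether DMBA/TPA changed a gene, relative to its acetone group, by more or less than DMBA did. It was called for 2460 genes, 1692 with the higher and 768 with the lower log2 response in DMBA/TPA. Flg responded more to DMBA/TPA by 3.18 on the log2 scale (adjusted p = 0.00504), and granular genes as a list did so in 15 of 21 cases (adjusted p = 1.96e-19; adjusted p = 0.0978 with an estimated correlation). Hyperplasia genes responded more in 12 of 19 cases (adjusted p = 7.27e-17; adjusted p = 0.204 with an estimated correlation) and mitosis genes in 3 of 20, 10 over the list alone (adjusted p = 5.62e-05; adjusted p = 0.483 with an estimated correlation). NRF2 targets did so in 9 of 17 cases (adjusted p = 5.78e-06; adjusted p = 0.204 with an estimated correlation). Interferon response genes responded less in 4 of 20 cases (adjusted p = 0.0057; adjusted p = 0.328 with an estimated correlation), a call lost without Control DMBA 1 (adjusted p = 0.0547) and Control DMBA TPA 1 (0.0611). Oasl2 responded less by 2.06 on the log2 scale (-2.06, adjusted p = 0.0227), a call lost without DMBA 1 and 2 and Control DMBA TPA 1 and 2 (adjusted p = 0.0642, 0.0926, 0.0933 and 0.0523), and Isg15 had -1.14 (adjusted p = 0.0994). T cell genes responded less in 9 of 20 cases (adjusted p = 1.89e-07; adjusted p = 0.22 with an estimated correlation), with Cd3e at -2.20 (adjusted p = 0.00373). Clock genes did so in 5 of 15 cases, 11 over the list alone (adjusted p = 5.78e-06; adjusted p = 0.204 with an estimated correlation). Cry2 had -0.90 (adjusted p = 0.0111), lost without DMBA 2 (0.0621) and Control DMBA TPA 2 (0.0572). Fibroblast, endothelial and hair shaft genes responded more in 9 of 13, 11 of 12 and 18 of 23 cases (adjusted p = 7.32e-18, 7.27e-17 and 2.65e-15; adjusted p = 0.204, 0.204 and 0.22 with an estimated correlation). The difference of responses also contains the gap between the acetone groups. In Control DMBA TPA against Control DMBA, the medians of these lists at the bound were -3.14, -3.18 and -5.67. For mitosis and clock genes they were -0.50 and 0.455. These larger or smaller responses thus rest in part on the acetone reference. The count of 2460 was 1104 without Control DMBA 2, 948 and 467 without DMBA 1 and 2, 550 and 669 without Control DMBA TPA 1 and 2, and 5359 without DMBA/TPA 1.

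DMBA/TPA set directly against DMBA, where regimen and harvest day cannot be separated, gave 2834 called genes, 1731 higher and 1103 lower. With total counts alone the split was 1402 higher and 1678 lower (45.5% higher in place of 61.1%), and the median of all genes moved from -0.016 to -0.135. Granular genes were higher in 19 of 21 cases (adjusted p = 6.83e-49; adjusted p = 0.0129 with an estimated correlation), and interferon response genes were lower in 8 of 20 cases and higher in 1 (adjusted p = 3.19e-05; adjusted p = 0.227 with an estimated correlation). The count was 708 and 461 without DMBA 1 and 2, 1830 and 1886 without Control DMBA TPA 1 and 2, 4866 without DMBA/TPA 1 and 1378 without DMBA/TPA 2.

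**Figure D4:**
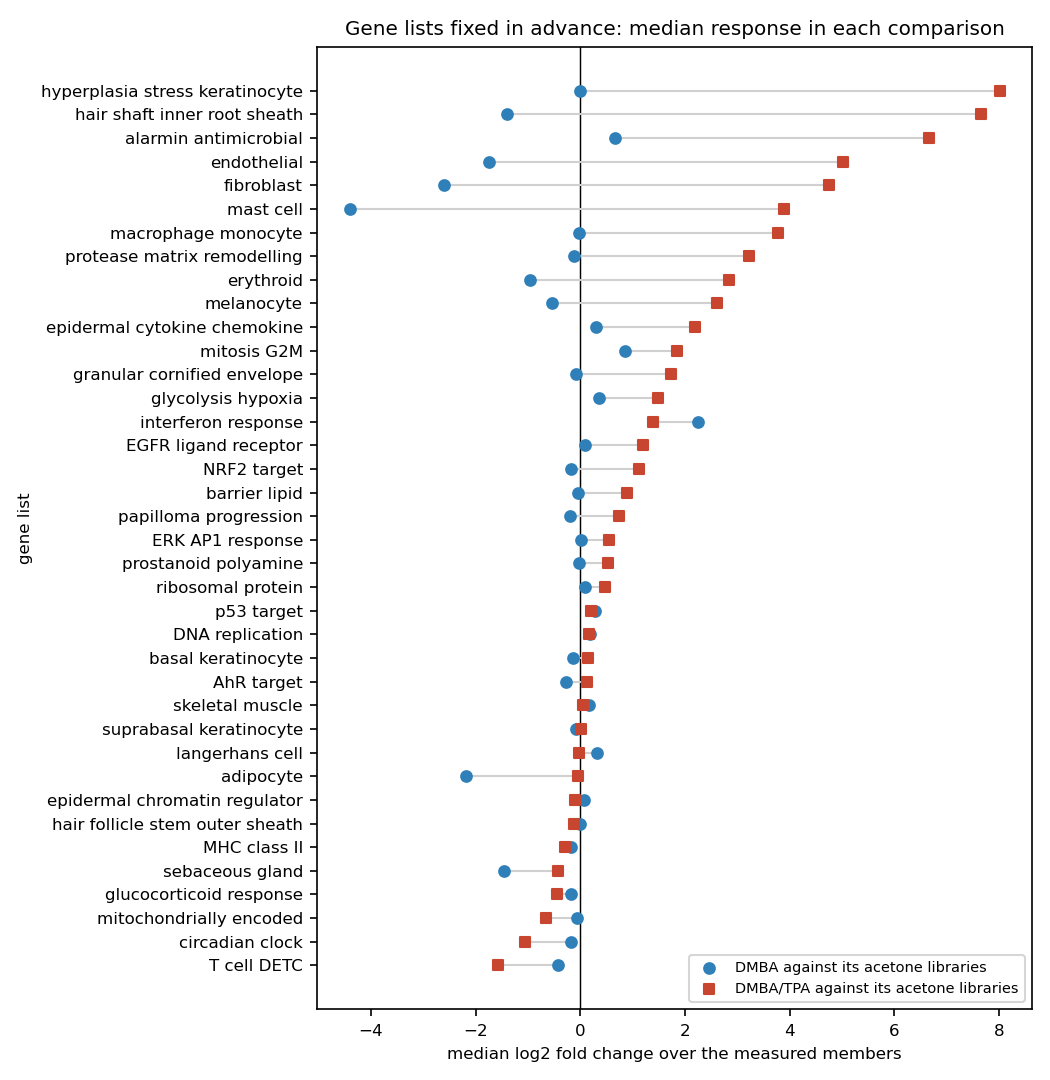
Median log2 fold change of each of 38 gene lists in DMBA (circles) and DMBA/TPA (squares) against their own acetone libraries, with members at 0 counts set at their bound. The interferon list is farthest right in DMBA (2.25), and fibroblast genes stand at -2.60 in DMBA and 4.76 in DMBA/TPA.

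The acetone groups were compared to show how far the reference of the regimens differed. Hair genes were far lower in Control DMBA TPA than in Control DMBA: with 0 counts in Control DMBA TPA, Krt72 was at least 612-fold lower (adjusted p = 0.0359), Krtap15 381-fold, Krtap7-1 359-fold, Krtap28-10 315-fold and Krtap4-16 289-fold. Hair shaft genes fell in 10 of 23 cases, 20 over the list alone (median -5.82, or -5.67 at the bound; adjusted p = 2.9e-15; adjusted p = 0.408 with an estimated correlation). Melanocyte genes fell in 5 of 11 cases, 8 over the list alone (median -1.80, adjusted p = 1.51e-05; adjusted p = 0.408 with an estimated correlation). Fibroblast genes fell in 8 of 13 (adjusted p = 6.84e-11) and endothelial genes in 4 of 12 cases (adjusted p = 5.3e-08), with adjusted p = 0.408 for both with an estimated correlation. Col3a1 had -7.67 (adjusted p = 0.00319), Col1a1 -4.44 (adjusted p = 0.0113) and Krt16 -2.65 (adjusted p = 0.0226). Higher in Control DMBA TPA were Scd3 (3.74 ± 0.32, adjusted p = 0.00265), Ifitm6 (2.71, adjusted p = 0.00646), Hamp2 (2.62, adjusted p = 0.0111), Serpinb6e (2.36, adjusted p = 0.0123) and Trpm3 (2.24, adjusted p = 0.0172). Granular genes were higher in 7 of 21 cases (adjusted p = 0.000303; adjusted p = 0.408 with an estimated correlation). Lists of mitosis, protease, macrophage and alarmin genes were lower in Control DMBA TPA by camera (adjusted p = 0.000307, 0.00256, 0.0173 and 0.0407). With an estimated correlation, 0 lists were called between the acetone groups. The protease median was 0 without Control DMBA 2. The test called 1216 genes, 383 higher and 833 lower in Control DMBA TPA. The count was 490 and 563 without Control DMBA 1 and 2, 655 and 651 without DMBA 1 and 2, 43 and 119 without Control DMBA TPA 1 and 2, and 2598 and 2572 without DMBA/TPA 1 and 2. Of 13 named genes, 2 and 4 kept their call without Control DMBA TPA 1 and 2, and 9 and 9 without Control DMBA 1 and 2. DMBA 1 or 2 left out ended the Krt72 call alone (adjusted p = 0.0545 and 0.0561).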

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

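The comparisons and the alternatives in this part were planned, except the other acetone group as control. The tests that weigh explanations were chosen only after the results were seen.

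The difference between the groups' responses was called for 2460 genes and for 25 of 38 gene lists, of which 0 were called with an estimated correlation. The genes with the largest fitted differences towards DMBA/TPA were Fabp4 (14.67 on the log2 scale), Krt72 (14.61), Krt26 (14.56), Col3a1 (14.26) and Krtap11-1 (13.39). Those of Fabp4, Krt72, Krt26 and Krtap11-1 rest on groups at 0 to 2 counts and are no bounds. The calls of Krt72, Krt26 and Krtap11-1 were lost without DMBA 1 (adjusted p = 0.0542, 0.0559 and 0.0641), DMBA 2 (0.0933, 0.093 and 0.12), Control DMBA TPA 1 (0.0833, 0.0792 and 0.111) and Control DMBA TPA 2 (0.0774, 0.0727 and 0.106), and that of Krtap11-1 also without Control DMBA 2 (0.0968). The largest in the other direction were Ifitm6 (-7.20), Lama1 (-5.77), Pyy (-5.47), Dab1 (-4.80) and Prf1 (-4.45).

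Col3a1 belongs to a wider pattern: dermal marker lists were called lower in DMBA and higher in DMBA/TPA than in the matching acetone libraries. In DMBA 2 of 13 fibroblast, 0 of 12 endothelial and 0 of 6 mast cell genes were called, the list calls were lost with an estimated correlation (adjusted p = 0.232, 0.233 and 0.232), and the fibroblast median was 0.68 against the other acetone group. In DMBA/TPA these list calls were lost with an estimated correlation too (adjusted p = 0.296, 0.31 and 0.352), and the erythroid list was not called (adjusted p = 0.141). The dermis is the layer that Dispase separation removes, and Col3a1 stood at 249, 3.60, 1.18 and 347 CPM in Control DMBA, DMBA, Control DMBA TPA and DMBA/TPA. Different amounts of dermis carried along with the sheets would move the fibroblast, endothelial, mast cell and erythroid lists together, and 9 of 9 medians of the latter lists had the sign of the fibroblast median. The comparisons share libraries, so these signs are not separate observations, and the adipocyte list, not called in DMBA/TPA (adjusted p = 0.763, 1 of 6 members called), had the other sign there (-0.15). Carry-over and an effect of the regimens on dermal cells both stay open. A lower share of keratinocyte RNA in DMBA/TPA would raise the markers of every other cell type. The T cell median was -1.57, so the markers of other cell types did not all rise. A fall of T cells themselves could outweigh such a lower share, so the test cannot exclude it.

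Krt72, Krt26 and Krtap11-1 belong to another pattern: hair shaft and inner root sheath genes were near 0 counts in Control DMBA TPA. Fewer follicles of any phase as the whole cause would lower the stem cell and outer sheath list about as much. That list was lower by far less (-0.834, MAD 0.742) than the shaft list (-5.67 with members at their bound). Without Control DMBA 1 its median was -0.39. The test cannot decide, since it was not tested whether the genes of that list come from follicles alone. Another hair cycle phase in these acetone libraries would also lower melanocyte genes, and their median was -1.80, with a MAD of 2.19 and a call that was lost with an estimated correlation (adjusted p = 0.408), so that explanation stays open. Whether DMBA/TPA itself raised hair shaft genes could not be told: against the other acetone group adjusted p = 0.148 and the median was 1.15.

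The interferon response genes, called higher as a list after DMBA, form the remaining pattern weighed. No single library alone carried the difference, since the list kept its call by camera at the preset correlation without each of 8 of 8 libraries. The estimated correlation was not tried with libraries left out. Since the 2 libraries of a group may come from the same animal, a difference carried by a single animal cannot be excluded. Unusually low levels in Control DMBA were excluded, since the median was 2.29 against the other acetone group. A larger share of immune cells of all kinds would raise the immune cell lists together. Their pooled median was -0.086 (MAD 0.815, 45 members, 19 higher and 26 lower), so their markers did not rise as a set. The list medians differed: -0.43 for T cell, 0.31 for Langerhans cell and -0.03 for macrophage genes. A fall of 1 kind could outweigh a rise of another, so the pooled test cannot exclude a changed share. A rise of cells of a single kind was not tested.

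Reads not aligned, a share that no comparison used, were 7.47% in DMBA 2, 9.82% in DMBA/TPA 1 and 16.4% in DMBA/TPA 2, above the highest acetone library (7.37%). Reads aligned to more than 1 place were 7.06% and 7.01% in DMBA 1 and 2 and 8.69% and 8.57% in DMBA/TPA 1 and 2, above the highest acetone library (6.92%).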

How the results depend on the processing

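The other acetone group as control was chosen only after the results were seen, and all other alternatives were planned. The counts of named results cover 12 alternatives run per gene and leave out the other acetone group as control. Of 180 named results that were called, 1991 alternative values kept direction and call and 169 kept the direction without the call. None of these values reversed. With the replicate block, 20 of the 24 named DMBA calls were lost. Against the other acetone group, 28 genes called in DMBA/TPA were called in the opposite direction. Of 24 not called, 261 stayed so, 19 gained a call and 8 reversed.

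The DMBA count of 52 genes stayed within 1.5 times with RLE factors (62), total counts (45), voom (46), the compared groups only (65), all acetone libraries (52) and a 2-fold minimum (48). It was 661 without the low-count filter, 428 by DESeq2 and 3210 against the other acetone group, and the cause was not tested. Of the 52, 48 were called in the same direction against that group and 0 in the opposite one. Leaving out 1 library gave 4 to 176. When a group is left with a lone library, that sample is assumed to vary like the other groups.

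The DMBA/TPA count of 7917 stayed within 1.5 times with RLE factors (7875), total counts (8164), no filter (8217), DESeq2 (7457), voom (7636) and the compared groups only (6058). It was 3860 at 2-fold or more, which follows from the stricter rule, 4632 with all acetone libraries as control and 3766 with the other acetone group, and the cause of the latter was not tested. Leaving out 1 library gave 3704 to 8901.

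The count of 2460 for the difference was 4041 without the filter and 467 to 5359 without 1 library. Between the acetone groups, 1216 became 743 at 2-fold, 2451 without the filter, 2051 by DESeq2, 1955 with the compared groups only and 43 to 2598 without 1 library. For DMBA/TPA against DMBA, 2834 became 1548 at 2-fold, 1812 with the compared groups only and 461 to 4866 without 1 library. Except for the stricter 2-fold rule, the cause was not tested. Total counts moved the median of all genes to -0.102 for the difference (from 0.004), and other scalings did not change these counts by more than 1.5 times.

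Of gene lists, 14, 24, 25 and 20 were called for DMBA, DMBA/TPA, the difference and the acetone groups. With an estimated correlation 1, 0, 0 and 0 were called, and with fry 2, 24, 18 and 0. The cause was not tested. Leaving out 1 library gave 13 to 20, 24 to 28, 23 to 28 and 17 to 23. On leaving out at least 1 library, 3, 2, 4 and 8 of the called lists lost their call and 14, 5, 6 and 5 of the others gained a call.

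With the sample number as a replicate block, the DMBA count was 5, and those of DMBA/TPA, the difference, the acetone groups and DMBA/TPA against DMBA were 7607, 2097, 834 and 2412. The cause was not tested. The differences between library 1 and library 2 correlated between groups at -0.152 to 0.035 over all genes tested. Equal sample numbers thus shared no shift over the genes as a whole. These values cannot exclude that such samples were handled together. With the block S100a8 in DMBA had 0.047.

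Over the alternatives run per gene, the reversed values all belong to genes that were not called. In DMBA, Hras ranged from -0.021 to 0.136, Krt6a from -0.088 to 0.528, Krt10 from -0.47 to 0.21 and S100a8 from -0.84 to 2.03 on leaving out 1 library, and S100a8 had 0.01 by DESeq2. S100a8 also turned to 0.49 without DMBA 2. In DMBA/TPA, Krt10 ranged from -0.324 to 0.007. The cause was not tested. Depth limits the genes near 0 counts in a group. Their folds are bounds where that group had 0 counts, and ratios with counting intervals where it had very few.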

Other observations

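The tests in this part were chosen only after the results were seen.

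Xist had 1294 to 3315 CPM in all libraries. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 34, 11, 33 and 36 counts in Control DMBA 1, 4, 1, 5 and 3 in Control DMBA 2, and 0 in the other 6 libraries.

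Fold change in DMBA/TPA went with the span of the gene. Among 14659 protein-coding genes with coordinates (75.4% of genes tested), the tenth with the shortest span (median 2.48 kb) had a median log2 fold change of 0.50, with 45.4% called higher and 7.3% lower. The tenth with the longest span (median 203 kb) had -0.19, with 16.3% higher and 32.3% lower. Against the other acetone group the medians were 0.16 and -0.15, between the acetone groups -0.27 and 0.06, and in DMBA 0.02 and -0.06. DMBA/TPA libraries had the largest shares of reads not aligned (9.82% and 16.4%), and Control DMBA TPA libraries the smallest (3.80% and 4.83%) and the largest shares of reads in no gene (41.2% and 42.1%).

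Summed CPM of the fibroblast list was 1965 and 954.5 in Control DMBA 1 and 2, 943.2 and 1034 in DMBA, 683.6 and 777 in Control DMBA TPA, and 1932 and 4308 in DMBA/TPA.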
